A study of Mus musculus with 3 samples.

How the data were processed

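Transcripts of a panel of 347 genes (247 of a standard brain panel and 100 added genes, per the file headers) were imaged in place with the Xenium platform, which decodes single RNA molecules in tissue from rounds of fluorescent probes. The samples were 3 coronal forebrain sections, each 10 um thick, from CD1 mice at postnatal day 7, per the labels. Per the labels the sections came from 2 brains, with 2 sections from 1 brain, and the labels do not say which sections share a brain. All 3 form 1 group, so no comparison between groups of samples was made, and every comparison was between regions of the same section.

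The deposited matrices hold counts of decoded transcripts per gene and segmented cell, per the file headers and the values. A rebuild of each matrix from the deposited transcript table, with transcripts of a quality score of at least 20 that were assigned to a cell, differed from the matrix by 0 transcripts in each section. The quality score in the deposited transcript table is a number per transcript, and the authors' platform counts a transcript from a score of 20. Positions, cell areas and an overlap flag for the nucleus were read from the deposited tables in um or as given. The software that drew the cell outlines and its version are not given in the sources used here.

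Cells with at least 10 transcripts were kept, which left 365468 cells and removed 3.56%, 3.26% and 4.96% of the cells of sections 1, 2 and 3. The medians were 52, 52 and 47 transcripts per cell, so that a single cell gives at most a presence or absence for most genes, and all tests of levels used sums over many cells. Totals of all genes per section correlated with r = 0.996 between sections 1 and 2, 0.989 between 1 and 3 and 0.995 between 2 and 3 (across genes, which are not independent replicates). As a check for files deposited in duplicate only, the counts of the same pairs were compared, and none was equal within sampling noise (chi-square of 180, 393 and 165 per degree of freedom). This does not make the sections independent, as 2 of them share a brain, and each was kept as a sample because the labels list it as one. No doublet caller was run, because cells were drawn in tissue and were not captured in droplets. Outlines that hold part of a neighbouring cell take the place of doublets here, and were treated through nuclear transcripts, the distance to the nearest cell and the neighbour criterion given further on.

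No annotation of cells was used from the authors. Counts per cell were scaled to the median total and log-transformed, 30 principal components were taken, and cells of all sections were clustered together with the Leiden method (15 neighbours, resolution 1) on 20000 cells per section, with the remaining cells assigned by nearest neighbours. A cluster was named with the ending "-like" from marker lists fixed before the data were examined. This needed at least 3 markers of the class among the cluster's leading genes, and more than of any other class. This gave 32 clusters, of which 1 was OPC-like (oligodendrocyte precursor cells), a class named from the OPC core and activated lists together. Its leading genes were Pdgfra, Cspg4, Gpr17, Olig2, Sox10, Olig1, Npas1, Sema3d, Gjc3 and Rgcc. Of these Gpr17 is on the committed precursor and Gjc3 on the oligodendrocyte list, so the class may hold committed precursors. Another cluster was oligodendrocyte or committed precursor-like, with its markers Mag, Enpp6, Gjc3, Gpr17, Mbp and Tmem163 among its leading genes. These genes define the classes, so their levels in them are not results on their own. Clusters without a sufficient marker set held 30.7% ± 0.637 (SD, n = 3) of the cells and stayed unnamed.

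Regions were set by clustering the summed counts of all cells within 50 um of each cell (20 principal components, 30 neighbours, 10000 cells per section). The 329 genes used left out the OPC core, the activated OPC genes other than Sox11, the committed precursor and the oligodendrocyte genes. Sox11, Mki67 and most other genes were therefore among the genes that set the regions, and OPC-like cells added to these sums, so an alternative set the regions from the other cells alone. Of 33 region clusters, the V-SVZ (ventricular-subventricular zone) joined 1 dorsolateral cluster led by Dlx2, Sp8 and Dlx1 with the wall clusters led by Foxj1 and Spag16. Upper cortex was led by Rorb and Cux2, among others. Deep cortex included layer 6b, led by Cplx3 and Ccn2. A glia-rich cluster of 10766 cells was assigned to the corpus callosum where it lay within 300 um of layer 6b, dorsolateral V-SVZ or the indusium and nearer to these than to upper cortex. It also took in white matter strips far from the midline, with 13.2% of the region's cells (681 of 5146) lying more than 1500 um from the V-SVZ.

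Counts of OPC-like cells were summed per section and region. The sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, section as a block, Benjamini-Hochberg adjustment within a comparison, adjusted p threshold of 0.05), in 1 fit of V-SVZ, corpus callosum and cortex and a separate fit of upper and deep cortex. The block was used because regions of a section come from the same animal. Genes needed at least 10 transcripts in at least 3 sums. The p-values treat the 3 sections as separate animals and are too small, because 2 of them share a brain. Gene lists with at least 3 tested genes were tested with camera in limma 3.58.1 (preset and estimated correlation between genes) and with fry, which left 16 lists. The panel was chosen for these cell types, so its other genes are not a neutral background for a list test.

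The lists were OPC core (5 of 5 genes on the panel), activated OPC (6 of 20), committed precursor (4 of 18), astrocyte (12 of 22), neural stem cell or radial glia (8 of 18), transit amplifying (6 of 9), neuroblast (8 of 15), ependymal (3 of 12), endothelial (17 of 17), mural (9 of 14), vascular leptomeningeal (13 of 15), microglia (13 of 18), cortical glutamatergic neuron (21 of 24), GABAergic interneuron (11 of 15), striatal projection neuron (6 of 12) and subcortical glutamatergic neuron (4 of 4). Lists for homeostatic OPC (0 of 25 genes on the panel), proliferation, cortical intermediate progenitor, oligodendrocyte and choroid plexus cells had too few tested genes for a list test. The activated list shares 2 genes, among them Egfr, with the transit amplifying list, Sox11 with the neuroblast list and Nes with the neural stem cell list.

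The genes named in each comparison followed a rule fixed before the data were examined. It took every tested member of the OPC core, activated, homeostatic, proliferation and committed precursor lists. It also took up to 8 genes per direction with the largest log2 fold change that passed the threshold, had the same sign in all 3 sections and met a neighbour criterion. That criterion required the CPM of the gene (its transcripts relative to all panel transcripts of the summed cells) in OPC-like cells, in the region where it was higher, to reach the CPM in all other cells of the region. Of the genes this rule takes, 1 is not reported here. Genes named outside the rule were chosen after their values were seen, and are said to be so where they appear.

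Shares of cell classes per region were compared with a two-sided exact sign-flip permutation test over sections, whose smallest p is 0.25 with 3 sections and 0.5 with 2 brains, so this design cannot reach the threshold. Shares of OPC-like cells with at least 1 transcript of a marker were computed after thinning each cell to 20 transcripts (10 for nuclear counts), as the exact expected share over all ways of thinning, with shallower cells left out and the unthinned share beside it. The rule of a random draw was replaced by this expectation after the data were seen. Shares in endothelial-like cells of the same region served as background, where at least 50 cells were present, and astrocyte-like cells were added as a further background after the data were seen. There were 12 marker genes and 36 such comparisons. CPM in OPC-like cells were also taken in bins of 200 um of distance to the nearest V-SVZ cell, up to 1400 um, with Spearman's rho over the 8 bins of each section.

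The test was checked on simulated counts with known changes in 100 of the genes. Recovery at a fold of 1.5 and of 3 was 56.8% and 90.5% for corpus callosum against cortex, 32.6% and 76.7% for V-SVZ against cortex, 18.4% and 75.6% for V-SVZ against corpus callosum, and 74.4% and 100% for upper against deep cortex. It made 4, 1, 4 and 4 calls among unchanged genes in the same order, and 0 calls in sets without changed genes. The simulated sums were drawn independently, without a section effect and with the same dispersion for all genes of a comparison. These rates therefore do not cover the sharing of a brain by 2 sections or a spread that differs between genes.

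The alternatives fixed beforehand were DESeq2 1.42.0, library totals in place of TMM, no filter on low counts, no block, nuclear transcripts only, a quality score of at least 30, a marker gate in place of the OPC-like cluster, a radius of 100 um, at least 20 transcripts per cell, a doubled clustering resolution, the neighbour criterion for all calls, each section left out in turn, and each pair of sections joined as 1 brain. The gate needed at least 2 Pdgfra transcripts, at least 1 of Sox10, Olig1 or Olig2, and none of Dcn or Col1a1. Of the OPC-like cluster's cells 71.3% met the gate, and 68.8% of the gate's cells lay in the cluster. By region 61.1% of the gate's cells lay in the cluster in the V-SVZ, 76.7% in the corpus callosum and 63.9% in the cortex. Added after the data were seen were cortex without layer 6b, cortex with layer 1, dorsolateral V-SVZ alone, regions set without OPC-like cells, nuclear transcripts together with the neighbour criterion, and a corpus callosum limited to 1500 um from the V-SVZ. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3. Images of the tissue were not analysed here.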

Results

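RNA of 347 genes was imaged in 3 coronal forebrain sections of CD1 mice at postnatal day 7, from 2 brains. The study, per its labels, set out to find where activated and homeostatic oligodendrocyte precursor cells (OPCs) lie in the ventricular-subventricular zone (V-SVZ), a germinal layer beside the lateral ventricle, in the corpus callosum and in the cortical grey matter. Sections 1, 2 and 3 held 130242, 124039 and 126119 segmented cells with 7795671, 7328132 and 6703178 transcripts, and medians of 52, 52 and 47 transcripts and 32, 32 and 29 genes per cell. Of the 25 homeostatic OPC genes listed beforehand 0 were on the panel, so levels of that state were not measured by its own list. The activated list was measured by 6 genes, among them Egfr, Dll3, Sox11, Rgcc and Nes.

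OPC-like cells, led by the receptor gene Pdgfra, the proteoglycan gene Cspg4 and the lineage transcription factor genes Olig1, Olig2 and Sox10, made up 5.61% ± 0.0967 (SD, n = 3 sections) of all cells, with 5.51% to 5.69% in single sections and 20521 cells in all. Oligodendrocyte or committed precursor-like cells, a class led by the myelin genes Mag and Mbp together with the committed precursor genes Enpp6 and Gpr17, made up 0.890% ± 0.0678. Astrocyte-like cells made up 10.8% ± 0.328 and cortical glutamatergic neuron-like cells 21.3% ± 0.667. OPC-like cells had a median of 39 transcripts, with 29 in the V-SVZ, 27 in the corpus callosum and 42 in the cortex. The sums of OPC-like cells per section held 182 to 213 cells and 5669 to 7708 transcripts in the V-SVZ, 397 to 425 cells and 12170 to 12459 transcripts in the corpus callosum, and 1893 to 2011 cells and 81501 to 94281 transcripts in the cortex.

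**Figure D1:**
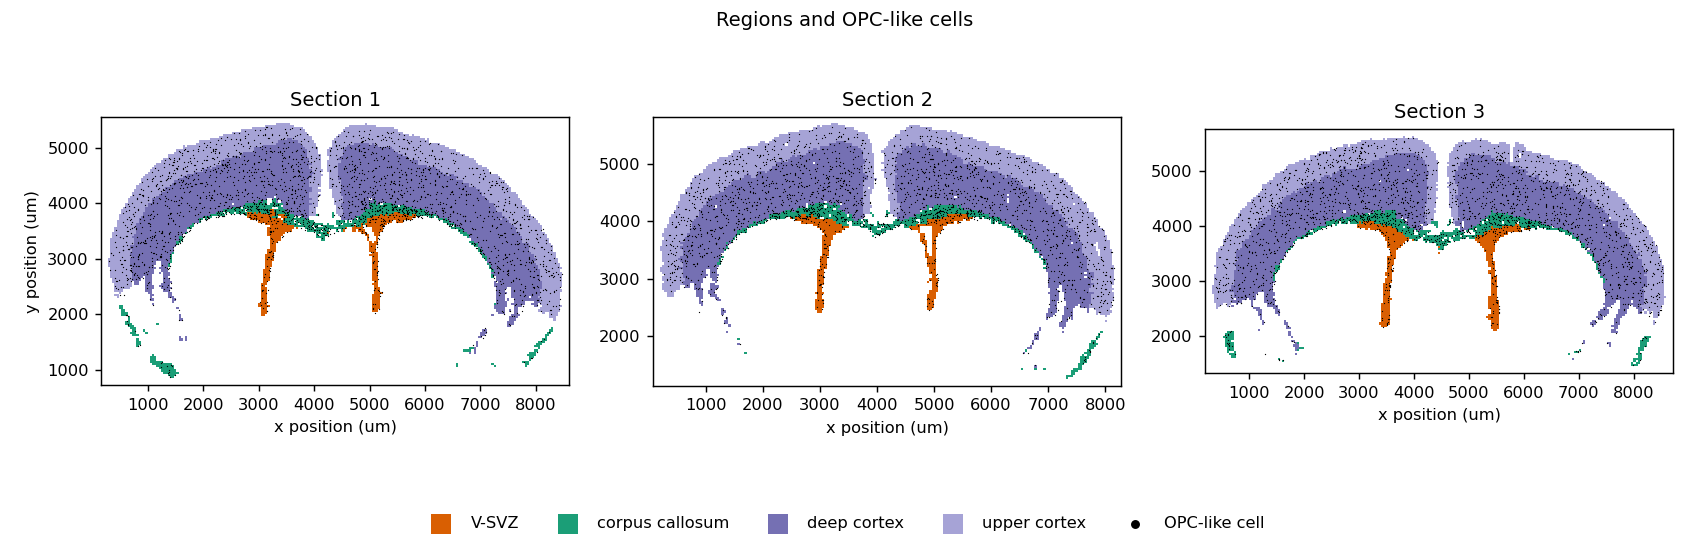
Position of the regions in each of the 3 sections, with x and y in um, coloured squares for V-SVZ, corpus callosum, deep and upper cortex, and black dots for OPC-like cells of these regions. The corpus callosum region arches over the V-SVZ and holds 1221 OPC-like cells, against 583 in the V-SVZ and 5845 in the cortex.

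The first comparison asked how densely the lineage occupied each region. OPC-like cells made up 23.7% ± 0.831 (SD, n = 3) of the cells of the corpus callosum, 5.01% ± 0.155 of the cortex and 3.40% ± 0.501 of the V-SVZ. The corpus callosum share exceeded that of the cortex by 18.7 ± 0.987 percentage points, and the V-SVZ share lay −1.61 ± 0.640 points from the cortex and −20.3 ± 0.496 points from the corpus callosum. Within the cortex the share was 3.60% ± 0.164 in upper and 6.33% ± 0.117 in deep layers, a difference of −2.74 ± 0.109 points. Oligodendrocyte or committed precursor-like cells made up 44.8% ± 0.903 of the lineage in the corpus callosum, 21.3% ± 3.53 in the V-SVZ and 12.1% ± 1.55 in the cortex, and 3.11% ± 0.504 in upper against 16.2% ± 1.96 in deep layers. Of the 744 such cells of deep cortex 567 lay in layer 6b, at its lower border. The whole cortex held 809, so this strip supplied most of the cells behind the deep and the cortical value. Each difference had the same direction in 3 of 3 sections and was larger than its SD. The exact two-sided sign-flip permutation test gave p = 0.25 for each, the smallest it can give with 3 sections, and since 2 of the sections share a brain even this p is too small. The corpus callosum region was recognised by its richness in glia, which favours a high share of glial cells in it.

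**Figure D2:**
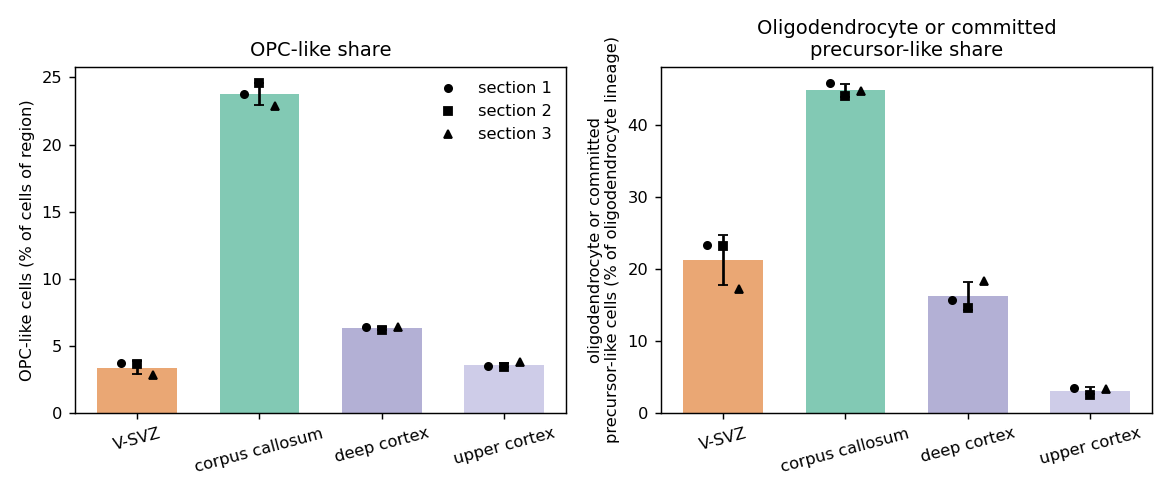
Left, OPC-like cells as percent of the cells of V-SVZ, corpus callosum, deep and upper cortex; right, oligodendrocyte or committed precursor-like cells as percent of oligodendrocyte-lineage cells, with bars for the mean of 3 sections, error bars for the SD and points for single sections. The OPC-like share stands at 23.7% in the corpus callosum and at 3.40% to 6.33% in the other regions.

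The next comparison set OPC-like cells of the corpus callosum against those of the cortex and asked whether white matter OPCs carry more of the activated genes. Dll3, which encodes a Notch ligand family member, rose by a log2 fold change of 3.24 (SE 0.18, adjusted p = 1.51e-16, n = 3 sections), from 729 ± 244 CPM in cortex to 6111 ± 1548 in the corpus callosum. It was higher in OPC-like cells than in the other cells of the corpus callosum, where it stood at 1010 CPM. The proliferation marker Mki67 rose by 1.63 (SE 0.11), from 3810 ± 431 to 10446 ± 1559 CPM.

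Of the 6 activated genes, 4 rose in the corpus callosum and 0 fell, and 4 passed when adjusted over the list alone. Egfr, the receptor gene for epidermal growth factor, rose by 1.79 (SE 0.15) and Nes, which encodes the intermediate filament nestin, by 1.56 (SE 0.17), but both had higher CPM in the neighbouring cells of the corpus callosum (9796 CPM for Egfr against 5850 in OPC-like cells). Sox11, at 0.28 (SE 0.14, adjusted p = 0.0840), and Rgcc, at −0.15 (SE 0.21, adjusted p = 0.568), did not pass. With nuclear transcripts Sox11 passed as higher (0.47, adjusted p = 0.0150), and it was higher in 2 of 3 sections. The list had a mean log2 fold change of 1.59 and an adjusted camera p of 0.00209, and adjusted p = 0.170 with an estimated correlation. Both proliferation genes rose, Hat1 by 0.89 (SE 0.21).

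Of the 4 committed precursor genes, listed to mark cells on the way to oligodendrocytes, 3 rose in the corpus callosum, also when adjusted over the list alone. Gpr17 rose by 0.73 (SE 0.12), from 13712 ± 2247 to 20077 ± 3293 CPM, and Fyn by 0.84 (SE 0.08). Fyn was not particular to the lineage. After thinning it was detected in 48.1% of cortical OPC-like, 48.7% of neuron-like and 37.5% of astrocyte-like cells. In the corpus callosum it was detected in 58.8% of OPC-like and 35.1% of astrocyte-like cells. Enpp6 rose by 2.96 (SE 0.28) but stood at 1964 CPM in OPC-like cells and at 13179 in the other cells of the region, and Tmem163 stood at 0.26 (SE 0.19, adjusted p = 0.249). The list's mean was 1.20 with an adjusted camera p of 0.0174, and adjusted p = 0.195 with an estimated correlation. It did not pass with nuclear transcripts (mean 0.62, adjusted p = 0.151), nor without section 1 or 2 (adjusted p of 0.127 and 0.177). Of the 5 OPC core genes, Sox10 (0.94, SE 0.11), Olig2 (0.71, SE 0.09) and Olig1 (0.67, SE 0.10) rose, Cspg4 fell (−0.26, SE 0.09, adjusted p = 0.0167) and Pdgfra did not pass (−0.05, SE 0.08, adjusted p = 0.635), with 4 passing when adjusted over the list alone. With nuclear transcripts Pdgfra passed as lower (−0.20, adjusted p = 0.0194). The core list had a mean of 0.40 and an adjusted camera p of 0.215. Cspg4 had the opposite direction, 0.34, when OPCs were taken by a marker gate.

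Among the genes that fell in the corpus callosum were Nrarp, Hes5 and Hes1, known targets of Notch signalling, a grouping made after their values were seen. Nrarp fell by 1.57 (SE 0.19, adjusted p = 1.33e-08), from 5429 ± 460 to 1615 ± 433 CPM, Hes5 by 1.49 (SE 0.33, adjusted p = 0.000305) and Hes1 by 1.09 (SE 0.35, adjusted p = 0.00896). Npas1 (−2.51, SE 0.25), Col19a1 (−2.07, SE 0.23), Epas1 (−1.21, SE 0.14), Lypd6 (−0.91, SE 0.18) and Cabp7 (−0.90, SE 0.36) also fell, and Cabp7 did not pass with nuclear transcripts, where its value was no smaller (−1.04, adjusted p = 0.0783). Genes that rose beside those named were Kcnmb2 (1.67, SE 0.12), Cd68 (1.53, SE 0.15), Foxj1 (1.52, SE 0.29), Kctd8 (1.46, SE 0.34) and Ntsr2 (1.36, SE 0.09). Cd68 is a microglia and macrophage marker, Foxj1 an ependymal and Ntsr2 an astrocyte marker.

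By edgeR's quasi-likelihood test 74 of 290 genes were higher and 84 lower in the corpus callosum, against 53 and 94 with library totals, a scaling that moved the median of all genes by −0.17. Of these genes, 38 of the higher and 71 of the lower did not meet the neighbour criterion. Marker lists of other cell types moved as well. The transit amplifying list (5 of 5 genes up, mean 1.83, camera adjusted p = 0.000361), the microglia list (7 of 12 up, 1 down, mean 1.03, adjusted p = 0.0174) and the astrocyte list (5 of 11 up, 1 down, mean 0.80, adjusted p = 0.0349) were higher, and the cortical glutamatergic neuron list was lower (16 of 21 down, 1 up, mean −1.39, adjusted p = 4.42e-05). With an estimated correlation their adjusted p were 0.170, 0.186, 0.189 and 0.186, so none passed. The microglia and astrocyte lists did not pass with nuclear transcripts (adjusted p of 0.184 and 0.312) either. Nor did the astrocyte list without section 1 or 2 (0.264 and 0.193), without the block (0.0549) or with a radius of 100 um (0.111), nor the microglia list without section 3 (0.0654). The other 9 lists did not pass. Their means were 1.01 for ependymal, 0.70 for leptomeningeal, 0.64 for endothelial, 0.64 for neuroblast, 0.55 for neural stem cell, 0.44 for mural, −0.11 for striatal, −0.17 for GABAergic and −1.13 for subcortical glutamatergic genes, with adjusted camera p from 0.150 to 0.877. Sox11, Mki67 and the genes outside the lineage lists also helped to set the regions, and the p-values are too small because 2 of the 3 sections share a brain. Without section 1, 2 or 3 there were 41, 41 and 51 higher and 47, 48 and 60 lower genes, and Cspg4, Gpr17 and Kctd8 did not pass without section 2, nor Hes1 without section 3.

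**Figure D3:**
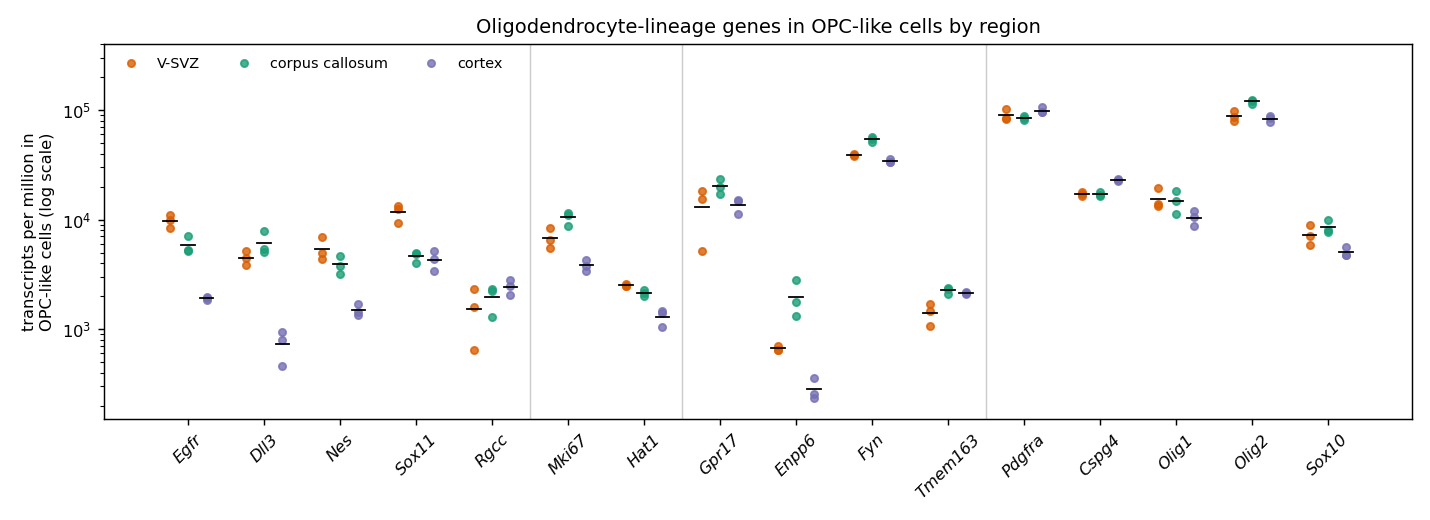
CPM (log scale) of 16 oligodendrocyte-lineage genes in OPC-like cells of the 3 regions, with a point per section and a bar at the mean, and vertical lines between activated, proliferation, committed precursor and core genes. Dll3 lies higher in V-SVZ and corpus callosum than in cortex (4467, 6111 and 729 CPM), and Pdgfra has 89711 CPM in the V-SVZ.

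OPC-like cells of the V-SVZ were then set against those of the cortex, to see whether OPCs in the germinal layer carry the activated genes. Of the 6 activated genes 5 rose and 0 fell. When adjusted over the list alone 6 passed, 5 as higher and Rgcc as lower. Dll3 rose by 2.64 (SE 0.23, adjusted p = 1.9e-11, n = 3), to 4467 ± 623 CPM against 716 in the other cells of the V-SVZ. Egfr (2.34, SE 0.16), Nes (1.86, SE 0.19) and Sox11 (1.44, SE 0.13) rose too, but their CPM in other V-SVZ cells was higher than in OPC-like cells (Egfr 10577 against 9739, Sox11 23622 against 11714). Rgcc stood at −0.64 (SE 0.28, adjusted p = 0.0708), was higher in 0 of 3 sections, and passed as lower with nuclear transcripts (−0.90, adjusted p = 0.00647). The list's mean was 1.70 with an adjusted camera p of 5.86e-05, and adjusted p = 0.0696 with an estimated correlation.

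Mki67 rose by 0.82 (SE 0.16) and Hat1 by 0.94 (SE 0.25) in the V-SVZ, and neither passed with nuclear transcripts (0.36 and 0.60, adjusted p of 0.0866 and 0.128). Both were higher in the other V-SVZ cells (Mki67 10663 against 6755 CPM, Hat1 5640 against 2506). Of the 4 committed precursor genes, Enpp6 rose (1.23, SE 0.48, adjusted p = 0.0405; 0.54 with nuclear transcripts, adjusted p = 0.532), and Gpr17 (−0.08, SE 0.14), Fyn (0.19, SE 0.09) and Tmem163 (−0.58, SE 0.27) did not pass; 0 passed when adjusted over the list alone. The list's mean was 0.23 (camera adjusted p = 0.848). Of the core genes Olig1 (0.59, SE 0.12) and Sox10 (0.55, SE 0.14) rose, Cspg4 fell (−0.43, SE 0.11) and Pdgfra (−0.14, SE 0.09) and Olig2 (0.08) did not pass, with 3 passing when adjusted over the list alone. With nuclear transcripts Pdgfra passed as lower (−0.28, adjusted p = 0.00162) and Fyn as higher (0.23, adjusted p = 0.0414). That list's mean was 0.13 (camera adjusted p = 0.848).

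Other genes were also higher in V-SVZ OPC-like cells. Nkx2-1, a ventral forebrain transcription factor gene, rose by 2.67 (SE 0.44), with Kctd8 (2.14, SE 0.36), Ppp1r1b (2.05, SE 0.20), Nrp2 (1.93, SE 0.48), Bcl11b (1.85, SE 0.28), Igf2 (1.41, SE 0.42; 0.51 with nuclear transcripts, adjusted p = 0.563) and Pde7b (1.39, SE 0.24). Ppp1r1b and Bcl11b are markers of striatal projection neurons, which adjoin the V-SVZ. Genes that fell were Col19a1 (−2.36, SE 0.30), Npas1 (−2.31, SE 0.30), Unc13c (−1.58, SE 0.33), Lypd6 (−1.58, SE 0.25), Epas1 (−1.17, SE 0.17), Acsbg1 (−1.14, SE 0.12), Ntsr2 (−1.04, SE 0.13) and Vcam1 (−0.78, SE 0.23; 0.03 under the marker gate). With nuclear transcripts the calls of Sox10 (0.28) and Vcam1 (−0.36) were lost as well. In all, 55 of 290 genes were higher and 64 lower, of which 35 and 50 did not meet the neighbour criterion.

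The transit amplifying (5 of 5 up, mean 2.34, camera adjusted p = 4.39e-06), neuroblast (6 of 8 up, 1 down, mean 2.05, adjusted p = 0.000109) and striatal projection neuron lists (5 of 6 up, mean 1.12, adjusted p = 0.000529) were higher in V-SVZ OPC-like cells, and the cortical glutamatergic neuron list was lower (14 of 21 down, 2 up, mean −1.34, adjusted p = 0.000529). With an estimated correlation the adjusted p were 0.0696, 0.0696, 0.154 and 0.237, so none passed, and with nuclear transcripts the glutamatergic list did not pass (adjusted p = 0.0557). The other 9 lists not yet given did not pass, with means from −0.84 (subcortical glutamatergic) to 1.11 (ependymal). The microglia list's mean was −0.04, its median 0.05 and its camera direction down, and the GABAergic list's mean was −0.02, its median −0.13 and its direction up. Markers of V-SVZ neighbours moved with the activated genes, and the p-values are too small because 2 of the 3 sections share a brain. Without section 1, 2 or 3 there were 31, 31 and 41 higher and 29, 27 and 45 lower genes; Enpp6 did not pass in any of these fits, nor Cspg4 and Sox10 without section 2, while Rgcc and Pdgfra passed as lower without section 3.

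V-SVZ and corpus callosum OPC-like cells were also compared directly. The activated list did not pass (mean 0.10, median −0.00, camera adjusted p = 0.647), with Sox11 (1.17, SE 0.16) and Egfr (0.55, SE 0.17, adjusted p = 0.0147) higher in the V-SVZ, Dll3 lower (−0.60, SE 0.20, adjusted p = 0.0294), and Nes (0.30) and Rgcc (−0.49) not passing; 3 passed when adjusted over the list alone. All 4 committed precursor genes were lower in the V-SVZ, also when adjusted over the list alone. Gpr17 fell by 0.80 (SE 0.15, adjusted p = 0.000112), Fyn by 0.65 (SE 0.10), Enpp6 by 1.74 (SE 0.40) and Tmem163 by 0.84 (SE 0.30, adjusted p = 0.0413). The list's mean was −0.97 (camera adjusted p = 0.00222; adjusted p = 0.126 with an estimated correlation and 0.0726 with nuclear transcripts). Mki67 fell by 0.80 (SE 0.15, adjusted p = 0.000135), and Hat1 (0.05) did not pass.

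Olig2 fell by 0.62 (SE 0.10) in the V-SVZ against the corpus callosum, and Sox10 (−0.39, adjusted p = 0.0667), Pdgfra (−0.09), Cspg4 (−0.16) and Olig1 (−0.08) did not pass, with 2 core genes passing when adjusted over the list alone (list mean −0.27, camera adjusted p = 0.0759). Ppp1r1b (2.14, SE 0.26), Bcl11b (2.06), Nkx2-1 (2.04), Ptprn (1.51), Pcp4 (1.32), Hes1 (1.30, SE 0.47, adjusted p = 0.0413), Gucy1a1 (1.15) and Nell1 (1.09) were higher in the V-SVZ. Ntsr2 (−2.40, SE 0.13), Slc17a7 (−2.76, from 2 and 23 transcripts in all), Cort (−2.08), Kcnmb2 (−1.81), Sema3d (−0.92) and Cd68 (−0.84) were lower. With nuclear transcripts 6 of the calls named for this comparison were lost. Hes1 (1.24) and Gucy1a1 (1.02) kept most of their value, Nell1 (0.61), Slc17a7 (−1.59) and Enpp6 (−0.99) kept less, and Tmem163 (−0.16) little, while Sox10 passed as lower (−0.55, adjusted p = 0.00743).

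In this comparison 35 of 290 genes were higher and 31 lower in the V-SVZ, of which 21 and 19 did not meet the neighbour criterion, against 43 and 22 with library totals, which moved the median of all genes by 0.17. The neuroblast list (8 of 8 up, mean 1.41, camera adjusted p = 4.11e-07) and the striatal list (4 of 6 up, mean 1.23, adjusted p = 1.34e-05) were higher, and the astrocyte (6 of 11 down, mean −1.12, adjusted p = 1.34e-05) and microglia lists (5 of 12 down, mean −1.07, adjusted p = 0.00472) were lower. With an estimated correlation the adjusted p were 0.0583, 0.0813, 0.0583 and 0.112, so none passed, and the astrocyte list did not pass with nuclear transcripts (adjusted p = 0.137), nor the microglia list without section 3 (adjusted p = 0.0833). The other 9 lists not yet given did not pass, with means from −0.41 (mural) to 0.52 (transit amplifying). Mean and median differed in sign for ependymal (0.10 and −0.58, camera down) and leptomeningeal genes (0.07 and −0.12, camera up). The V-SVZ sums were the shallowest, and the p-values are too small because 2 of the 3 sections share a brain. Without section 1, 2 or 3 there were 20, 16 and 28 higher and 10, 8 and 23 lower genes; Dll3, Tmem163, Gucy1a1 and Nell1 passed in none of these fits, and Gpr17 and Fyn did not pass without section 2, nor Slc17a7 without section 1. Calls of Mki67, Enpp6, Olig2, Cort, Sema3d and Cd68 were lost without section 1 and without section 2, and those of Egfr and Hes1 without section 2 and without section 3.

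A last gene comparison set OPC-like cells of the upper cortical layers against those of the deep layers, within grey matter. Mki67 was higher in upper layers by 0.94 (SE 0.12, adjusted p = 2.17e-08, n = 3), with 5403 ± 888 against 2904 ± 559 CPM. Dll3 was lower by a log2 fold change of −1.81 (SE 0.26, adjusted p = 4.47e-07), with 272 ± 72 against 986 ± 343 CPM. Of the other activated genes Sox11 was higher (0.31, SE 0.10), and Egfr (−0.25), Nes (0.35) and Rgcc (0.28) did not pass. Gpr17 (−0.31, SE 0.07) and Tmem163 (−0.42, SE 0.14) were lower and Fyn higher (0.13, SE 0.05), while Enpp6 (−0.78) and Hat1 (−0.14) did not pass. Of the core genes Cspg4 (0.26, SE 0.05) and Pdgfra (0.10, SE 0.04) were higher, Olig2 was lower (−0.15, SE 0.04), and Olig1 (−0.03) and Sox10 (−0.21) did not pass.

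Other genes higher in upper-layer OPC-like cells were Col19a1 (0.98, SE 0.11), Thbs4 (0.93), Vcam1 (0.50), Acsbg1 (0.44), Nfkb1 (0.39), Slc1a3 (0.33) and Epas1 (0.32). Lower were the astrocyte marker Gfap (−1.84, SE 0.30; 221 ± 57 against 810 ± 82 CPM), Carmn (−0.75), Tox (−0.74), Kcnmb2 (−0.59), Cd68 (−0.59) and Ntsr2 (−0.55). In all, 61 of 271 genes were higher and 61 lower, of which 49 and 48 did not meet the neighbour criterion. With nuclear transcripts the calls of Sox11 (0.24), Cspg4 (0.15), Tmem163 (−0.15), Nfkb1 (0.33), Carmn (−0.73) and Cd68 (−0.50) were lost, Fyn moved to −0.02 and Pdgfra to −0.00, while Egfr (−0.73, adjusted p = 0.0181) and Sox10 (−0.30, adjusted p = 0.0268) passed as lower. Under the marker gate Egfr was 0.30, in the opposite direction, and the p-values are too small because 2 of the 3 sections share a brain. Without section 1, 2 or 3 there were 43, 43 and 31 higher and 37, 43 and 30 lower genes; Sox11, Nfkb1 and Pdgfra passed in none of these fits, and Mki67 (1.02), Gpr17, Olig2, Cspg4 and Slc1a3 did not pass without section 3. Calls of Thbs4, Carmn and Cd68 were lost without section 1 and without section 3, those of Fyn and Tmem163 without section 2 and without section 3, that of Epas1 without section 1 and without section 2, and that of Vcam1 without section 2.

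Per cell, 11.4% ± 3.32 (SD, n = 3) of corpus callosum OPC-like cells had a Dll3 transcript after thinning to 20 transcripts, against 8.43% ± 1.24 in the V-SVZ and 1.60% ± 0.449 in the cortex. Endothelial-like cells of the same regions had 0.979%, 0.305% and 0.176%, astrocyte-like cells 1.15%, 0.332% and 0.238% and neuron-like cells of the cortex 0.387%, so Dll3 stood above background in each region. For Mki67 the shares were 14.9% ± 1.44, 9.88% ± 2.19 and 5.35% ± 0.580 in the same order, with 3.55%, 8.51% and 6.02% in endothelial-like cells, 2.75%, 3.94% and 1.85% in astrocyte-like cells and 0.751% in neuron-like cells of the cortex. The cortical share lay below the first background and above both others by more than its SD. Whether endothelial-like cells carry Mki67 of their own was not tested, so its standing against stray transcripts was left open. The V-SVZ share exceeded the first background by less than its SD and was left open as well. Unthinned shares in the same order were 16.4%, 12.9% and 3.03% for Dll3 and 17.6%, 13.2% and 8.95% for Mki67. The corpus callosum exceeded the cortex by 9.78 ± 2.90 points for Dll3 and 9.56 ± 1.17 for Mki67.

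Egfr was detected in 15.9% ± 2.59 of V-SVZ, 9.37% ± 1.21 of corpus callosum and 3.54% ± 0.125 of cortical OPC-like cells, against 10.0%, 7.42% and 3.30% of endothelial-like and 28.6%, 24.3% and 25.3% of astrocyte-like cells, and 2.58% of neuron-like cells of the cortex. Egfr was among the leading genes of the largest astrocyte-like cluster, so the share in these cells may be their own. Sox11 was detected in 19.8% ± 4.10, 9.33% ± 1.26 and 8.32% ± 1.81, against 16.4%, 3.06% and 4.95% of endothelial-like cells, 14.1%, 5.11% and 6.91% of astrocyte-like cells and 11.4% of neuron-like cells of the cortex, so that the cortical share lay below a background, and the V-SVZ share exceeded the first by less than its SD. Nes was at 10.4%, 7.74% and 2.98%, against 23.5%, 19.1% and 21.2% of endothelial-like cells, 10.1%, 5.92% and 2.97% of astrocyte-like cells and 1.35% of neuron-like cells of the cortex. These backgrounds differ too much to place the Nes shares. Unthinned, Egfr was at 21.5%, 13.2% and 7.37%, Sox11 at 29.0%, 12.4% and 17.1%, and Nes at 16.0%, 10.9% and 6.13%. Gpr17 was detected in 19.4% ± 8.12, 29.4% ± 3.93 and 22.9% ± 3.35 (unthinned 29.1%, 39.0% and 40.5%), with 1.20%, 1.78% and 0.770% in endothelial-like cells, 1.53%, 3.07% and 0.857% in astrocyte-like cells and 0.560% in neuron-like cells of the cortex. Without thinning, the corpus callosum share lay below the cortical share for Sox11 and Gpr17, the opposite of the thinned order, so no order was read for these genes. Median depths of endothelial-like cells were 34, 45 and 47 transcripts, against 29, 27 and 42 in OPC-like cells. Thinning left out 147, 365 and 763 cells of V-SVZ, corpus callosum and cortex, and the exact sign-flip permutation test gave p = 0.25 at best in the 36 comparisons, a p that is too small because 2 of the 3 sections share a brain.

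By distance to the nearest V-SVZ cell, summed CPM of the activated list in OPC-like cells went from 38716 ± 2088 (SD, n = 3) inside the V-SVZ to 30898 ± 3067 within 200 um, 17510 ± 918 from 200 to 400 um and 10867 ± 1990 from 1200 to 1400 um. Spearman's rho over the 8 bins was −1, −0.93 and −0.98 in sections 1, 2 and 3. Among its genes Rgcc did not follow (0.67, 0.93 and −0.21), while Egfr (−0.93, −0.83 and −0.88), Dll3 (−0.98, −0.74 and −0.95) and Sox11 (−0.55, −0.52 and −0.55) had negative rho. So did the committed precursor list (−0.90, −0.81 and −0.48) and the core list (−0.64, −0.0952 and −0.55), so a negative rho was not limited to activated genes. The committed precursor list rose from 53556 CPM inside the V-SVZ to 80472 within 200 um before it fell. Inside the V-SVZ Fyn alone had 37611 to 39310 CPM in single sections, so the sum of this list was mostly Fyn there. The core list had 217201 CPM inside and 221204 in the farthest bin, so it did not decline from the V-SVZ outward. Its mean rho was positive with nuclear transcripts. Dll3 was highest within 200 um outside the V-SVZ, at 7186 ± 1709 CPM, against 4467 ± 623 inside and 608 ± 216 in the farthest bin. Mki67 had 10223 ± 2126 CPM within 200 um and 6755 ± 1420 inside, was lowest at 400 to 600 um (2201 ± 407) and stood at 5167 ± 1995 in the farthest bin, with rho of −0.24, −0.64 and −0.55. Pdgfra had 89711 CPM inside and 100432 ± 9563 in the farthest bin (rho 0.40, 0.81 and 0.60). The cells inside the V-SVZ are those of the region comparisons (182 to 213 per section), so the profile is not independent of these comparisons. Bins outside the V-SVZ held 197 to 378 cells per section and cover only part of the OPC-like cells (7087 in section 1). The bin within 200 um resembled the corpus callosum (Mki67 7783 to 11673 against 8668 to 11577 CPM, Dll3 6081 to 9154 against 5057 to 7888). The decline and the peak of Dll3 may therefore largely repeat the comparison of corpus callosum with cortex. No test was made across cells or bins.

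**Figure D4:**
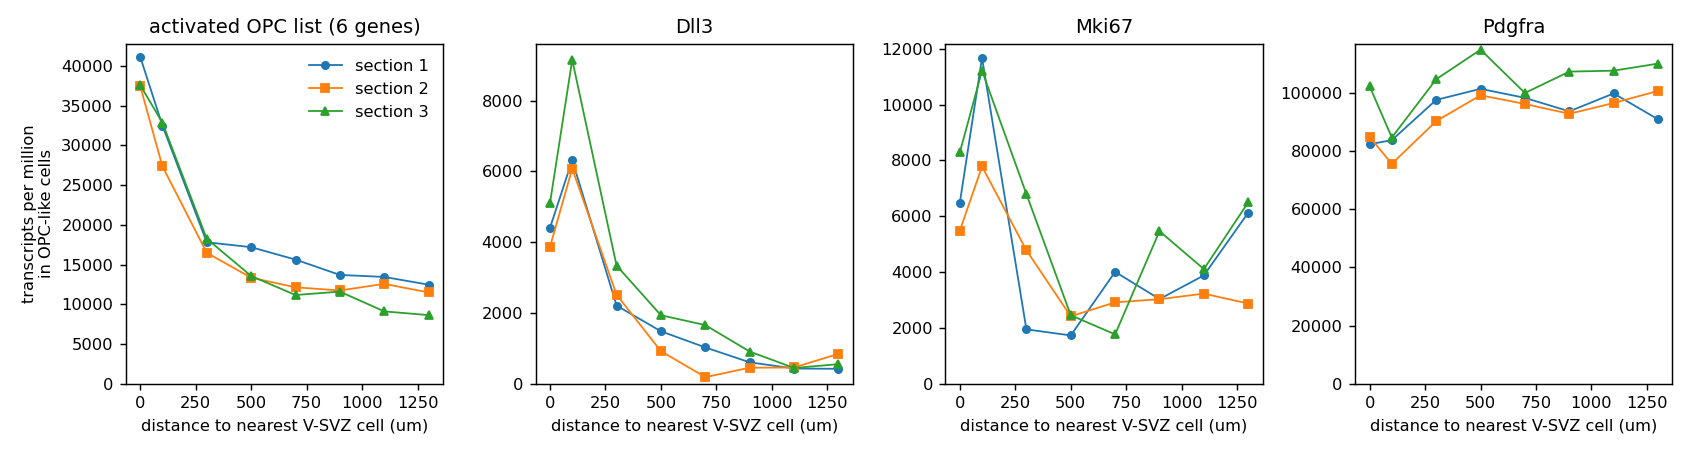
CPM in OPC-like cells against distance to the nearest V-SVZ cell (um) for the activated list, Dll3, Mki67 and Pdgfra, with a line per section; the point at 0 is the V-SVZ itself. The activated list declines from 38716 to 10867 CPM, and Dll3 peaks at 7186 CPM in the first bin outside the V-SVZ.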

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

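The counts over other splits of the sums were chosen only after the results were seen. Transcripts of the negative control probes, which match no mouse gene and enter none of the comparisons, were present in each section. They made up 0.108% of the decoded transcripts in cells in section 1 (8414 counts), 0.144% in section 2 (10575 counts) and 0.166% in section 3 (11119 counts). Counts of 0 would allow shares of up to 3.84e-05%, 4.09e-05% and 4.47e-05%, a limit of 3 counts that covers counting error only. Per control probe this came to 312, 392 and 412 counts, and no explanation was tested for the difference between sections.

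Each comparison of 2 regions has 6 sums of OPC-like cells, which can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Fitted to those 6 sums alone with the section as a block, the real split of corpus callosum and cortex gave 145 genes past the threshold, that of V-SVZ and cortex 121, that of V-SVZ and corpus callosum 60 and that of upper and deep cortex 122. The highest of the other splits gave 0 genes in each, so that 1 split, the real one, gave a count as large.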

How the results depend on the processing

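The settings with layer 6b left out, layer 1 added, dorsolateral V-SVZ alone, the corpus callosum limited to its part near the V-SVZ, regions set without OPC-like cells, and nuclear transcripts joined with the neighbour criterion were chosen only after the results were seen. Of the values of main results under an alternative, 807 counted as the same, 51 moved, 30 were weaker, 1 was stronger and 17 reversed. What counted as the same differed by kind of result. A gene list or a single gene kept its direction and its side of the threshold, and a count of genes or lists stayed within 1.5 times. A difference in shares only kept its sign, and a class share or rho kept its sign and moved by less than its error. Of the values of single named genes, 2166 were the same, 205 weaker, 45 stronger and 45 reversed. With DESeq2 14 gene calls were weaker and 0 reversed, and no count of genes moved by over 1.5 times. With regions set without OPC-like cells 6 gene calls were weaker, 1 stronger and 0 reversed. With cortex taken with layer 1, 4 were weaker and 1 stronger. The cause was not tested for any change given here, unless the setting itself shows it. V-SVZ sums, with 583 OPC-like cells and 19572 transcripts in all, limit the comparisons they enter.

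The section as a block follows the design, since regions of a section come from 1 animal. In the fit with no replicate block 17 gene calls were weaker, the astrocyte list of corpus callosum against cortex no longer passed (adjusted p = 0.0549), and it changed no other call of a main result.

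With camera's estimated correlation 0 lists passed in each of 3 comparisons. Adjusted p for V-SVZ against cortex were 0.0696 for the activated, neuroblast and transit amplifying lists, 0.237 for cortical glutamatergic and 0.154 for striatal genes. For corpus callosum against cortex they were 0.170 (activated and transit amplifying), 0.189 (astrocyte), 0.195 (committed precursor) and 0.186 (cortical glutamatergic and microglia). For V-SVZ against corpus callosum they were 0.0583 (astrocyte and neuroblast), 0.126 (committed precursor), 0.112 (microglia) and 0.0813 (striatal). With fry, which asks whether a list's genes move on balance 1 way, 9 lists passed for V-SVZ against cortex and 14 for corpus callosum against cortex, where OPC core passed (adjusted p = 0.00672).

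With nuclear transcripts only, V-SVZ against corpus callosum gave 22 higher genes, V-SVZ against cortex 36 higher and 36 lower, and upper against deep cortex 38 and 33. Log2 fold changes reversed for V-SVZ against corpus callosum in Cspg4 (0.0145), Hat1 (−0.19) and Olig1 (0.13), for V-SVZ against cortex in Olig2 (−0.0729), for corpus callosum against cortex in Tmem163 (−0.14), and for upper against deep cortex in Fyn (−0.0176) and Pdgfra (−0.00106). Marker-positive shares reversed for Fyn, V-SVZ minus cortex (0.591 points), Hat1, V-SVZ minus corpus callosum (−0.177) and Tmem163, corpus callosum minus cortex (−0.211). The mean rho of the OPC core by distance was 0.310. Adjusted camera p were 0.727 for OPC core in V-SVZ against cortex (reversed), 0.0557 for cortical glutamatergic there, 0.137 for astrocyte and 0.0726 for committed precursor in V-SVZ against corpus callosum, and 0.312, 0.151 and 0.184 for astrocyte, committed precursor and microglia in corpus callosum against cortex. In each of the comparisons with the corpus callosum 3 lists passed.

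With the neighbour criterion for all genes there were 40 higher and 13 lower for corpus callosum against cortex, 18 and 12 for V-SVZ against cortex, 9 and 10 for V-SVZ against corpus callosum, and 12 and 17 for upper against deep cortex. Joined with nuclear transcripts these were 27 and 16, 14 and 17, 6 and 12, and 7 and 11. Among the calls made with all genes, those that meet the criterion numbered 36 and 13, 20 and 14, 14 and 12, and 12 and 13 in the same order. The counts under this setting differ from these, as dispersions and adjusted p were computed again over the genes left. The joined setting reversed Cspg4 (0.0144), Hat1 (−0.19) and Olig1 (0.13) in V-SVZ against corpus callosum, Tmem163 (−0.14) in corpus callosum against cortex, and Fyn (−0.0176) in upper against deep cortex. It also reversed 2 further values, OPC V-SVZ vs cortex: Olig2 log2 fold (−0.0733) and OPC upper vs deep cortex: Pdgfra log2 fold (−0.000942).

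With the marker gate 96 genes were higher in upper cortex. Log2 fold changes reversed for Vcam1 (0.0337) in V-SVZ against cortex, Cspg4 (0.34) and Rgcc (0.30) in corpus callosum against cortex, and Egfr (0.30) in upper against deep cortex. So did the value for OPC V-SVZ vs cortex: Fyn log2 fold (−0.0551). The Rgcc share of V-SVZ minus corpus callosum was 0.167 points, the activated list's mean rho by distance −0.865, and the committed precursor list of V-SVZ against cortex reversed (adjusted p = 0.972).

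With a radius of 100 um, Nes (−0.20), Pdgfra (0.0211) and Rgcc (0.0274) reversed in V-SVZ against corpus callosum, as did OPC corpus callosum vs cortex: Tmem163 log2 fold (−0.0475). The Rgcc share of V-SVZ minus corpus callosum was 0.374 points, and the difference in OPC marker-positive shares by region: Tmem163, corpus callosum minus cortex was −0.406. The activated list of V-SVZ against corpus callosum reversed (adjusted p = 0.951), and the astrocyte list of corpus callosum against cortex had adjusted p = 0.111.

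The value for OPC V-SVZ vs corpus callosum: Hat1 log2 fold reversed with at least 20 transcripts per cell (−0.0794), with the corpus callosum near the V-SVZ only (−0.0377) and with a quality score of at least 30 (−0.000866). Library totals reversed OPC V-SVZ vs corpus callosum: Cspg4 log2 fold (0.00467), and in the same comparison Olig1 (0.0846) and Pdgfra (0.0799). Joining sections 1 and 2 as 1 brain reversed Cspg4 (0.00965), Olig1 (0.10) and Pdgfra (0.10), joining 1 and 3 reversed Olig1 (0.0627) and Pdgfra (0.0359), and joining 2 and 3 Olig1 (0.0239). Dorsolateral V-SVZ alone gave 17 higher genes against the corpus callosum and reversed Gpr17 (0.0636) against cortex. Without the filter on low counts the value for OPC V-SVZ vs cortex: Olig2 log2 fold was −0.0429. Cortex without layer 6b reversed Olig1 (0.0492) in upper against deep cortex.

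Without thinning, 4 differences in marker-positive shares reversed, and cortical OPC-like cells were deeper. They were OPC marker-positive shares by region: Fyn, corpus callosum minus cortex (−2.30 points), OPC marker-positive shares by region: Sox11, corpus callosum minus cortex (−4.66), OPC marker-positive shares by region: Tmem163, corpus callosum minus cortex (−2.48), and the same for Gpr17 (−1.47). With at least 20 transcripts per cell the cell class shares by section: OPC-like, astrocyte-like and oligodendrocyte or committed precursor-like, were on average 5.31%, 10.3% and 0.821%, and with a doubled resolution the OPC-like and oligodendrocyte or committed precursor-like shares were 5.85% and 0.959%.

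Leaving out each section in turn, which leaves fewer sums, gave 41 to 51 higher and 47 to 60 lower genes in corpus callosum against cortex, 31 to 41 and 27 to 45 in V-SVZ against cortex, 16 to 28 and 8 to 23 in V-SVZ against corpus callosum, and 31 to 43 and 30 to 43 in upper against deep cortex. Log2 fold changes ranged from −0.13 to 0.0903 for Pdgfra and −0.11 to 0.0596 for Olig1 in V-SVZ against corpus callosum, and from −0.38 to 0.12 for Gpr17 in V-SVZ against cortex. Values for OPC V-SVZ vs cortex: Olig2 log2 fold ranged from −0.0136 to 0.12, and for OPC upper vs deep cortex: Pdgfra log2 fold from −0.00696 to 0.10. The difference in OPC marker-positive shares by region: Fyn, V-SVZ minus cortex ranged from −0.692 to 0.0351 points. Adjusted camera p ranged from 0.838 to 0.943 for OPC core and 0.912 to 0.936 for committed precursor in V-SVZ against cortex, from 0.0479 to 0.264 for astrocyte, 0.0479 to 0.177 for committed precursor and 0.0143 to 0.0654 for microglia in corpus callosum against cortex, and from 0.0161 to 0.0833 for microglia in V-SVZ against corpus callosum.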

Other observations

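The tests of neighbouring transcripts on the activated genes, both tests on Hes1, Hes5 and Nrarp, and the choice of those 3 genes came only after the results were seen, and the tests of other cell types and of neuronal genes were written before. Germinal and glial regions differed in their makeup beside the oligodendrocyte lineage. Neuroblast-like cells made up 41.5% ± 2.75 (SD, n = 3 sections) of the dorsolateral V-SVZ and 12.8% ± 1.26 of the ventricular wall, while neural stem cell or radial glia-like cells made up 29.5% ± 3.96 and 49.8% ± 0.620. That class (8942 cells) also had the ependymal markers Foxj1 and Spag16 among its leading genes. At a doubled clustering resolution an ependymal-like cluster of 3653 cells stood apart, beside stem cell-like clusters of 5518 and 341 cells, so the share of the wall is not that of stem cells alone. OPC-like cells held 4.26% ± 0.722 of the dorsolateral V-SVZ and 2.80% ± 0.449 of the wall, and oligodendrocyte or committed precursor-like cells 1.95% ± 0.535 and 0.240% ± 0.138. These regions were set by genes of the same cell types, so their shares describe the borders drawn and were not tested.

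In the corpus callosum 24.2% ± 0.870 of cells were astrocyte-like, 19.3% ± 0.797 oligodendrocyte or committed precursor-like and 8.46% ± 0.903 microglia-like, against 2.57% ± 0.260 microglia-like cells in the cortex. Layer 6b, at the lower border of the cortex, held 9.15% ± 0.555 OPC-like and 6.57% ± 0.968 oligodendrocyte or committed precursor-like cells. The septum held 8.88% ± 0.216 OPC-like cells but 0.476% oligodendrocyte or committed precursor-like cells, and the striatum 4.92% ± 0.118 and 0.893% ± 0.110. Layer 1 held 10.98% ± 1.04 OPC-like, 41.2% ± 0.590 astrocyte-like and 17.2% ± 1.85 endothelial-like cells. It was set as the part of the glia-rich cluster that lay within 300 um of upper cortex and nearer to it. Like the corpus callosum, layer 1 was thus recognised by its richness in glia, which favours a high share of glial cells in it. A cluster led by Kcnj13 and Clic6, genes of the choroid plexus, stayed unnamed and had 87, 139 and 2 cells in sections 1, 2 and 3.

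Summed over the list, activated genes were higher in OPC-like cells of the corpus callosum and the V-SVZ than of the cortex. Rgcc did not pass in either comparison (−0.15 and −0.64), but passed as lower in the V-SVZ with nuclear transcripts (−0.90, adjusted p = 0.00647), against the direction of the list. Sox11 did not pass in the corpus callosum (adjusted p = 0.0840), but did with nuclear transcripts (0.47, adjusted p = 0.0150), and the list did not pass with an estimated correlation (adjusted p = 0.170 and adjusted p = 0.0696). In cells farther than the median from the nearest cell, with nuclear transcripts only, the log2 ratio of the summed list was 1.15 ± 0.30 (SD over sections) against 1.28 over all cells for the corpus callosum (610 cells), and 1.39 ± 0.15 against 1.70 for the V-SVZ (291 cells). The limit as first written, at least 0.8 of the whole ratio and a value above its SD, was met by both and would have argued against transcripts from neighbours. It was tightened after the values were seen, so that the limit had to be passed by more than the SD. Neither ratio did so, and transcripts from neighbours remain open as part of the difference. Single genes went different ways in the V-SVZ, with Dll3 from 2.67 to 1.64 ± 0.67, Nes from 1.84 to 0.91 ± 0.48, Sox11 from 1.44 to 1.32 ± 0.22 and Egfr from 2.34 to 2.73 ± 0.54. In the corpus callosum Dll3 went from 3.10 to 2.71 ± 0.23, Nes from 1.38 to 0.73 ± 0.11 and Egfr from 1.60 to 1.64 ± 0.25. In cells with no transcript of the other progenitor and astrocyte lists the ratio was 0.83 ± 0.61 (55 cells) and 1.68 ± 0.48 (41 cells), too few cells to decide on cells of another type, under a minimum of 100 cells set after the counts were seen. No biological explanation was tested, as the samples form 1 group.

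Hes1, Hes5 and Nrarp were lower in OPC-like cells of the corpus callosum than of the cortex, with a log2 ratio of −1.71 ± 0.38 for their sum. With nuclear transcripts of cells farther than the median from the nearest cell the ratio was −1.78 ± 0.26 (610 cells), so it did not shrink. The same split by distance changed the neuronal list in cortical OPC-like cells by a log2 ratio of only −0.0483. How many neighbouring transcripts this selection removes is not known, so the test cannot decide on them. The ratio of −1.78 rests mostly on Nrarp (−1.86 ± 0.65) and Hes5 (−2.34 ± 0.18), as Hes1, with 15 transcripts over all corpus callosum OPC-like cells, gave no value there. Hes5 was near the floor as well, with 13, 3 and 2 transcripts in all corpus callosum OPC-like cells of sections 1, 2 and 3. Its SD therefore does not measure its counting error. Nrarp alone did not pass the limit by more than its SD, and neighbouring transcripts remain open for the sum and for each gene taken singly. With regions set without OPC-like cells the ratio of the sum was −1.80 ± 0.43 (1197 cells). Of the 1221 OPC-like cells of the corpus callosum 1160 kept their region, so the counts of OPC-like cells themselves had little effect on the borders. Counts of these genes in the other cells still helped to set the regions, so the test cannot decide on borders drawn with these genes. In the V-SVZ, where Dll3 was also higher than in the cortex, the ratios over all cells were −0.74 ± 0.30 for Nrarp, −0.75 ± 1.29 for Hes5 and 0.13 ± 0.40 for Hes1. Cells of another type in the class were not tested for these genes, and no biological explanation was tested.

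Neuronal genes were higher in OPC-like cells of the cortex than of the corpus callosum, with a mean log2 fold change of −1.39 for the glutamatergic list. Of its 21 genes 16 were lower in the corpus callosum, 1 was higher and 4 did not pass, and the list did not pass with an estimated correlation (adjusted p = 0.186). In cortical OPC-like cells farther than the median from the nearest cell (2922 cells) the summed list was lower than in the nearer cells, by a log2 ratio of −0.0483 ± 0.0326. This has the direction that transcripts of neighbouring neurons predict and exceeds the SD, so such transcripts may contribute. The ratio is small beside the −1.39 of the list, and it does not show how much of that shift they account for.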
